A study of Mus musculus with 30 samples.

How the data were processed

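The whole hippocampus of both sides was taken from hemizygous 5XFAD mice, offspring of transgenic males and C57BL/6J females, at 1, 2 and 4 months of age, frozen, and used for total RNA. Per the labels, polyadenylated RNA was isolated and libraries were made with a NEBNext Ultra kit that does not mark the strand. ERCC spike-ins were added, and the libraries were sequenced in 3 pools. Pool membership and the strand setting of the read counting are not given in the sources used here, and the spike-ins were not used. Wild-type libraries, which the authors' tables compare with 5XFAD, are not analysed here.

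The submitters' processing notes name Trimmomatic 0.32, TopHat2 2.0.13, SAMtools, DESeq2 1.8.1 and Cufflinks 2.1.1 and the mouse build GRCm38/mm10. The counting tool and the annotation release are not given in the sources used here. The deposited count table holds raw read counts of 37315 genes in 30 libraries, of which 1452 have no symbol, with 0 unused per-sample columns and 0 entries naming no gene. A second deposited table holds FPKM values for the same libraries, and 12 genes of the count table are absent from it. The deposited comparison tables hold the authors' mean normalized signal over the libraries of their model, a log2 fold change with its standard error, a p and an adjusted p. The terms of the authors' models, any shrinkage of the deposited fold changes and the protein measurement are not stated. The 6 deposited RNA tables give 1 mean normalized value per gene in all of them. The deposited qPCR values are the authors' ratio of each target to Eif4h or Gapdh, computed from deposited threshold cycles. In the sheet of cycles 2 entries read PSEN2 and PSEN3 in the column of targets but PSEN1 in the full label of the same row, and they were taken as PSEN1. Positions of named genes are those of GENCODE vM21 on GRCm38, joined by Ensembl gene identifier.

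Total counts ranged from 4.09 M to 12.6 M in 1-month females, 9.58 M to 19.5 M in 1-month males. They ranged from 6.43 M to 15.8 M in 2-month females, 6.01 M to 11.7 M in 2-month males, and from 9.80 M to 16.8 M in 4-month females and 7.92 M to 14.6 M in 4-month males. Counting intervals are given at 95% for genes with few counts in a group, and they cover counting error only.

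Each library was assigned to 1 of 6 groups of 5 animals by the age and sex in its label. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at a minimum count of 10, which left 16549. Libraries were normalised by TMM (factors 0.972 to 1.02). A quasi-likelihood F test with robust estimates was run on all 30 libraries with 1 coefficient per group. The common biological coefficient of variation was 0.0734. Adjusted p are Benjamini-Hochberg values over the genes tested in a comparison, with 0.05 as the threshold and no limit on the fold. Sex was compared at each age (females against males), age was compared within each sex (4 against 1, 4 against 2 and 2 against 1 months), and an interaction term compared the change from 1 to 4 months between females and males. Levels are CPM with TMM factors, as mean ± SD of 5 animals, and log2 values for scores used a prior count of 2. Replicate numbers in the titles are not stated to pair animals. Correlations between libraries of the same number in 2 groups exceeded 0.1 in 9 of 45 pairs of libraries, 3 of them between the sexes at 4 months, and no pairing was used.

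The 28 gene lists cover plaque-associated microglia, homeostatic microglia, complement, antigen presentation, interferon, reactive astrocytes, astrocytes, neurons, interneurons, oligodendrocytes, oligodendrocyte precursors, vascular cells, choroid plexus, meningeal fibroblasts, ependyma, neighbouring brain regions, hippocampal subfields, immediate early genes, neurogenesis and proliferation, cholesterol synthesis, glucocorticoid response, amyloid processing, nuclear oxidative phosphorylation, mitochondrially encoded genes, blood, X escape, Y-linked and transgene-related genes. They were tested with camera of limma 3.58.1, two-sided, with the inter-gene correlation preset at 0.01 and again with it estimated, for lists with at least 3 tested members, and adjusted over the lists of a comparison. Members passing were also counted with p adjusted over the list alone. A list score is the mean log2 CPM of its members.

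The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Named genes were, per comparison, the 10 with the largest log2 fold change in each direction among those passing with a mean of at least 1 CPM, up to 4 members of each list with the lowest p, and App, Psen1, Thy1, Xist and the Y-linked list throughout, with Xist and the sex-linked lists given apart in the comparisons of sexes. For the authors' tables the rule takes the 10 entries with the lowest adjusted p, App, Psen1, Thy1 and the list members described. Fewer may be printed where the text would become a list, and none were chosen outside the rule without saying so.

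Alternatives fixed in advance were DESeq2 size factors, no filter and a stricter filter, the replicate number as a block, the choroid plexus score as a covariate, and the libraries of a comparison alone. Also fixed were the animal-code prefix as a block where both sexes share prefixes, DESeq2 1.42.0, limma-voom with quality weights, camera with an estimated correlation, a minimum fold of 1.5 in the authors' tables, and each library left out in turn. The fits with the prefix as a block used only the libraries of the comparison. Chosen after seeing the data were limma on log2 of FPKM plus a pseudocount of 1, leaving out the 2 libraries under 100 CPM of Ttr or the 3 under 7 M counts, list tests with these libraries out or with blocks, and an equal qPCR efficiency of 2. Other splits of the samples, 100 per comparison with the real split included, were refitted with the same edgeR steps.

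The edgeR steps were tested on simulated data with 50 genes changed at each fold. For 5 against 5 libraries drawn on the values of the sexes at 4 months (16434 genes), 26, 41, 46 and 50 of 50 were recovered at folds of 1.25, 1.5, 2 and 4, with 10 false among 173 calls. In a second draw, for 4 against 1 month in females (16425 genes), 28, 45, 44 and 50 were recovered, with 7 false among 174 calls. Camera gave a raised list of 20 genes p of 1.1e-53 and 9.6e-62 in the same settings and an unchanged list 0.830 and 0.484. The simulated genes were drawn independently, so this check does not cover false list calls that arise from correlation between genes.

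The qPCR values of 2 females and 2 males were compared by an exact two-sided permutation test, and the correlation of Thy1 with the plaque-associated score by 100000 permutations (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). Figures were drawn with matplotlib 3.10.9.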

Results

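RNA from the hippocampus of 30 5XFAD mice was sequenced, 1 library per animal. The animals were females and males aged 1, 2 and 4 months, with 5 in each of the 6 groups. 5XFAD mice are hemizygous transgenic animals that carry human APP and human PSEN1 with familial Alzheimer's disease mutations under the neuronal Thy1 promoter. They develop amyloid plaques. Total counts over annotated genes ranged from 4.09 M to 19.5 M per library with a median of 11.9 M. After the filter on low counts 16549 of 37315 genes were tested. Wild-type libraries are not analysed here, so a difference between ages covers ordinary maturation as well as any effect of the transgenes. The animal codes in the labels begin with a numeric prefix whose meaning is not stated. No prefix occurred at more than 1 age, so prefixes are nested in age. The mean log2 CPM of plaque-associated microglial genes lay at 4.906, 4.901 and 4.797 in the females of the 3 prefixes of 4 months and at 3.387, 3.270 and 3.481 in those of 2 months.

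Expression of sex-linked genes matched the labelled sex of all 30 libraries. Xist, the RNA that silences an X chromosome, lay between 810 and 1122 CPM (counts per M total counts) in females and between 0.746 and 2.51 CPM in males. The Y-linked genes Eif2s3y, Kdm5d and Ddx3y lay at 38.6 to 66.6, 18.6 to 25.8 and 68.1 to 87.9 CPM in males. In females Eif2s3y did not exceed 0.497 CPM. Mouse App, the precursor of amyloid beta, and mouse Psen1, the catalytic subunit of gamma-secretase, did not pass in any of the 10 comparisons of the edgeR fit (adjusted p from 0.403 to 0.988 for Psen1 and from 0.495 to 0.999 for App). App stood at 1157 ± 32.0 CPM in females and 1122 ± 29.4 CPM in males of 4 months (mean ± SD, n = 5). Thy1, whose promoter drives the transgenes, rose between 1 and 4 months from 1847 ± 178 to 2338 ± 166 CPM in females (edgeR adjusted p = 2.7e-04) and from 1756 ± 131 to 2076 ± 185 CPM in males (edgeR adjusted p = 0.00744). Thy1 did not pass between the sexes at 4 months (log2 ratio 0.17, edgeR adjusted p = 0.224). In the authors' deposited tables Thy1 was higher in 5XFAD than in wild type, by 1.70 at 1 month and 1.97 at 4 months on the log2 scale. Its counts here can therefore not be taken as those of the endogenous gene alone.

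Between 1 and 4 months, female hippocampus gained transcripts of plaque-associated microglia, complement, antigen presentation and the interferon response, and lost transcripts of myelinating oligodendrocytes and immature neurons. Cst7 (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944 on GRCm38), an inhibitor of lysosomal cysteine proteases made by microglia around plaques, went from 0.0821 ± 0.116 to 26.6 ± 2.74 CPM (mean ± SD, n = 5). With 3 counts in the 1-month females against 1718 at 4 months, its ratio was 440 with a 95% counting interval of 150 to 2135. Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), a lipid receptor of microglia, rose from 7.71 ± 1.70 to 39.3 ± 3.31 CPM (log2 fold change 2.41, SE 0.109, edgeR adjusted p = 1.2e-20). Cldn11 (ENSMUSG00000037625, chromosome 3, 31149920 to 31164324), the tight junction protein of myelin, fell from 368 ± 32.9 to 145 ± 6.24 CPM (log2 fold change −1.34, SE 0.0598, edgeR adjusted p = 6.3e-20). Of the 16549 genes, 1150 rose and 1126 fell in females. Among them 283 rose and 41 fell by more than 2-fold.

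Of 30 plaque-associated microglial genes tested in females, 25 rose, also 25 when adjusted over the list alone, with a median log2 change of 1.48 (camera adjusted p = 7.5e-120, and 4.3e-10 with an estimated correlation). Clec7a, a receptor for fungal glucans that plaque-associated microglia express, rose from 0.359 ± 0.275 to 16.9 ± 2.92 CPM. The chemokine Ccl6 rose from 1.59 ± 0.407 to 16.5 ± 1.39 CPM. Itgax, an integrin subunit, had 1 count in the 1-month females against 335 at 4 months, a ratio of 257 (95% counting interval 45.9 to 10194). Of 16 homeostatic microglial genes 15 rose, among them Gpr34, a lysophosphatidylserine receptor, from 13.8 ± 2.03 to 33.5 ± 1.87 CPM, and Csf1r, the receptor that keeps microglia alive, from 64.0 ± 1.42 to 117 ± 6.28 CPM. The median of that list was 1.06 (camera adjusted p = 2.6e-61). In the complement list 9 of 15 genes rose (10 adjusted over the list alone, median 1.10, camera adjusted p = 3.4e-40). C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882), an opsonin precursor, rose from 11.8 ± 1.29 to 90.2 ± 5.94 CPM (edgeR adjusted p = 3.8e-18). The recognition subunits C1qa, C1qb and C1qc rose by 1.86, 1.73 and 1.68 on the log2 scale. How reads shared by C4b and its close paralog C4a were counted is not given in the sources used here. Of 20 antigen presentation genes 19 rose (19 adjusted over the list alone, camera adjusted p = 6.7e-34). B2m, the light chain of MHC class I, rose from 58.3 ± 3.85 to 161 ± 16.2 CPM. All 25 interferon-responsive genes rose (25 adjusted over the list alone, median 1.15, camera adjusted p = 8.9e-37), Ifit3 going from 8.29 ± 1.70 to 28.6 ± 7.41 CPM. Each of these lists also passed with an estimated correlation.

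Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the intermediate filament of astrocytes, rose in females from 306 ± 5.91 to 856 ± 49.3 CPM (log2 fold change 1.49, edgeR adjusted p = 5.8e-21). The reactive astrocyte list passed with 8 of 21 genes risen and a median of 0.13 (camera adjusted p = 2.2e-07, and 0.0052 with an estimated correlation). Serpina3n, a serine protease inhibitor, rose from 35.2 ± 3.54 to 62.7 ± 1.00 CPM. General astrocyte markers did not pass as a list (camera adjusted p = 0.339).

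Of 22 oligodendrocyte genes 16 fell and 4 rose in females (17 fell adjusted over the list alone, median −0.96, camera adjusted p = 9.2e-44, and 1.0e-04 with an estimated correlation). Plp1, the main protein of central myelin, fell from 4591 ± 366 to 1975 ± 66.0 CPM, and Mog, a protein of the outer myelin surface, fell by 1.29 on the log2 scale. Of 16 oligodendrocyte precursor genes 10 fell (13 adjusted over the list alone, median −0.37, camera adjusted p = 8.1e-14, and 1.0e-04 with an estimated correlation). Gpr17, a receptor of cells about to differentiate, fell from 125 ± 8.38 to 55.1 ± 4.39 CPM. The neurogenesis and proliferation list lost 10 of 16 genes (11 adjusted over the list alone, median −0.58, camera adjusted p = 1.3e-17, and 6.9e-06 with an estimated correlation). Marcksl1, an actin regulator of growing neurites, fell from 120 ± 6.37 to 59.2 ± 4.03 CPM, and Dcx, a microtubule protein of newborn neurons, from 43.8 ± 4.60 to 28.2 ± 1.28 CPM. The extracellular matrix genes Eln and Col3a1 fell by 2.35 and 2.25 on the log2 scale.

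Males changed in the same groups between 1 and 4 months, with 1735 genes risen and 1596 fallen in the edgeR fit. On FPKM 937 rose and 1476 fell (median of all genes −0.027). Of the genes that rose, 674 were shared with females against 121 by chance, and of those that fell 653 against 109. A further 13 went opposite ways. Cst7 went from 0.103 ± 0.111 to 16.8 ± 1.71 CPM (mean ± SD, n = 5), a ratio of 189 from 6 and 1046 counts (95% counting interval 86.5 to 516). Trem2 rose from 7.52 ± 1.18 to 28.4 ± 4.28 CPM (log2 fold change 1.89, edgeR adjusted p = 1.3e-17). Of the lists, plaque-associated microglia had 24 of 30 genes risen (25 adjusted over the list alone, median 1.16, camera adjusted p = 8.9e-71). Homeostatic microglia had 15 of 16 (median 0.67, camera adjusted p = 8.0e-31). Complement had 6 of 15 risen (7 adjusted over the list alone, median 0.68, camera adjusted p = 2.6e-18). Antigen presentation had 12 of 20 (15 adjusted over the list alone, median 0.93, camera adjusted p = 7.3e-16), and the interferon list 20 of 25 (23 adjusted over the list alone, median 0.81, camera adjusted p = 4.8e-17). All 5 lists also passed with an estimated correlation. C4b rose from 13.5 ± 2.89 to 62.4 ± 10.9 CPM and Gfap from 321 ± 29.8 to 695 ± 84.9 CPM. Of the reactive astrocyte list 11 of 21 genes rose and 1 fell (median 0.45, camera adjusted p = 1.6e-06, and 0.0111 with an estimated correlation).

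In males the oligodendrocyte list again held 16 fallen genes and 3 risen (median −0.99, camera adjusted p = 4.7e-42, and 1.4e-04 with an estimated correlation). Cldn11 fell from 362 ± 29.5 to 141 ± 11.9 CPM and Plp1 from 4434 ± 486 to 1978 ± 248 CPM. Oligodendrocyte precursors lost 13 of 16 genes (14 adjusted over the list alone, median −0.40, camera adjusted p = 4.7e-16, and 4.2e-05 with an estimated correlation). The neurogenesis list lost 9 (11 adjusted over the list alone, median −0.51, camera adjusted p = 1.9e-17, and 2.3e-05 with an estimated correlation), Dcx falling from 46.8 ± 4.01 to 24.2 ± 3.02 CPM. The structural RNA Rn7sk, a regulator of transcription elongation, and the iron-binding lipocalin Lcn2 passed in males with spreads larger than their means. The values were 42.2 ± 77.8 CPM against 5.02 ± 2.29 for Rn7sk (edgeR adjusted p = 0.00905) and 5.07 ± 7.79 CPM against 0.533 ± 0.408 for Lcn2 (edgeR adjusted p = 0.0157). Without replicate 2 of the 4-month males neither passed (edgeR adjusted p = 0.570 for Rn7sk, with a range of 7.1e-04 to 0.570 over 20 alternatives, and 0.240 for Lcn2).

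Several lists passed in the 4-month against 1-month comparisons only with the preset correlation. Vascular markers lost 5 of 20 genes in females (camera adjusted p = 0.0076, adjusted p = 0.413 with an estimated correlation). In males 3 fell and 1 rose (camera adjusted p = 0.0457, adjusted p = 0.655 with an estimated correlation). Meningeal fibroblast markers lost 3 of 17 in females (median −0.28, camera adjusted p = 0.0038, adjusted p = 0.465 with an estimated correlation). In males they lost 5 (median −0.41, camera adjusted p = 3.9e-04, adjusted p = 0.412 with an estimated correlation). Of 5 blood genes 4 fell in each sex. Their median was −0.85 in females (camera adjusted p = 1.1e-04, adjusted p = 0.156 with an estimated correlation) and −1.15 in males (camera adjusted p = 1.6e-06, adjusted p = 0.0585 with an estimated correlation). Of 13 mitochondrially encoded genes 7 rose in females (11 adjusted over the list alone, median 0.21, camera adjusted p = 3.9e-05, adjusted p = 0.413 with an estimated correlation). In males 5 rose (median 0.13, camera adjusted p = 0.0093, adjusted p = 0.673 with an estimated correlation). In females cholesterol synthesis had 5 of 19 genes fallen and 1 risen (median −0.18, camera adjusted p = 0.0128, adjusted p = 0.584 with an estimated correlation). In males 2 went each way (camera adjusted p = 0.789). In males immediate early genes had 5 of 22 risen and 1 fallen (camera adjusted p = 0.0346, adjusted p = 0.690 with an estimated correlation). Nuclear genes of oxidative phosphorylation had 7 of 39 fallen in males (median −0.06, camera adjusted p = 0.0257, adjusted p = 0.655 with an estimated correlation). Choroid plexus markers had a median of −0.36 in males with no member passing (camera adjusted p = 0.0190, adjusted p = 0.728 with an estimated correlation). In females their median and mean were both 0.05 while the direction of the test was down (camera adjusted p = 0.987). Of 10 fits without 1 library, cholesterol synthesis in females lost its call in 4 and vascular markers in males in 5. In males choroid plexus, immediate early and nuclear oxidative phosphorylation genes lost theirs in 3 each.

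The remaining lists did not pass by camera between 1 and 4 months. In females the adjusted p was 0.0670 for neuronal markers, where Syp, a synaptic vesicle protein, and Stmn2, a tubulin regulator of neurites, were among 5 of 19 fallen genes (log2 fold changes −0.25 and −0.24). It was 0.440 for interneurons, 0.502 for ependyma, 0.980 for neighbouring brain regions, 0.885 for hippocampal subfields, 0.339 for immediate early genes, and 0.0670 for glucocorticoid-responsive genes. It was 0.737 for amyloid processing, 0.0670 for nuclear oxidative phosphorylation genes, 0.841 for genes that escape X inactivation and 0.339 for the transgene-related list. In males the camera adjusted p was 0.271 for neuronal markers, 0.798 for interneurons, 0.776 for astrocytes, 0.286 for ependyma, 0.798 for neighbouring brain regions, 0.448 for hippocampal subfields, and 0.329 for glucocorticoid-responsive genes. It was 0.535 for amyloid processing, 0.798 for X escape genes, 0.271 for Y-linked genes and 0.535 for the transgene-related list. Within amyloid processing, Bace1, the beta-secretase, fell by 0.23 in females and 0.20 in males on the log2 scale. Clu, an apolipoprotein that binds amyloid beta, rose by 0.31 and 0.25.

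**Figure D1:**
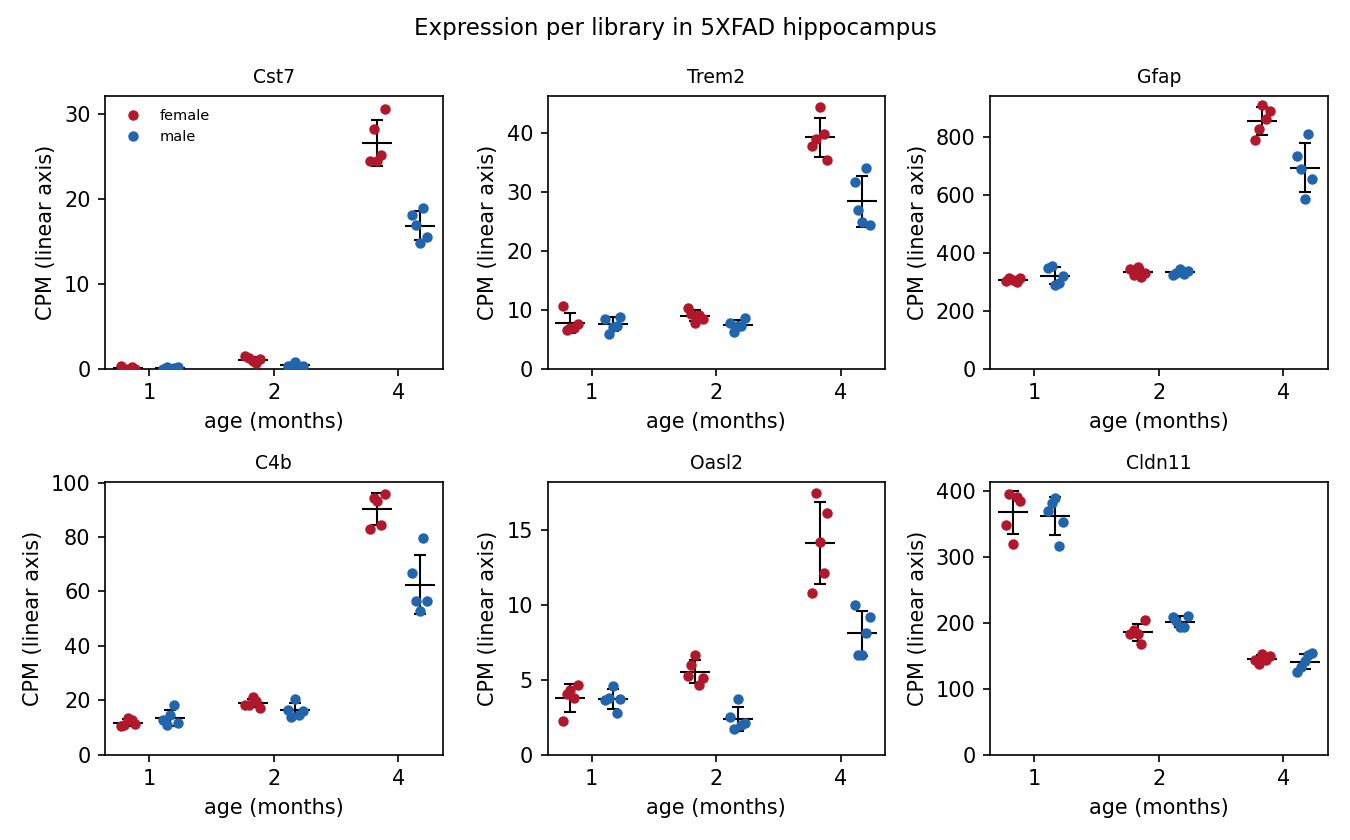
Expression in CPM on a linear axis of Cst7, Trem2, Gfap, C4b, Oasl2 and Cldn11 in the 30 libraries, with age in months and sex on the horizontal axis. Each point is a library, and bars give the mean ± SD of 5 animals. Cldn11 lies at a mean of 368 CPM in females and 362 CPM in males at 1 month and at 145 and 141 CPM at 4 months, while Cst7 has a mean of 1.05 and 0.368 CPM at 2 months.

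Between 2 and 4 months microglial, complement and reactive astrocyte genes rose in both sexes. In females Cst7 rose from 1.05 ± 0.314 to 26.6 ± 2.74 CPM (mean ± SD, n = 5, edgeR adjusted p = 4.9e-23) and Trem2 from 8.99 ± 0.946 to 39.3 ± 3.31 CPM. C4b rose from 18.9 ± 1.57 to 90.2 ± 5.94 CPM and Gfap from 333 ± 14.5 to 856 ± 49.3 CPM. In males Cst7 rose from 0.368 ± 0.241 to 16.8 ± 1.71 CPM (edgeR adjusted p = 1.2e-20), Trem2 from 7.42 ± 0.866 to 28.4 ± 4.28 CPM and Gfap from 333 ± 8.79 to 695 ± 84.9 CPM. The edgeR fit called 490 genes higher and 123 lower in females and 486 higher and 217 lower in males. Of these, 295 risen genes were shared between the sexes (14.4 by chance) and 39 fallen genes (1.61 by chance). Itgax had 8 counts at 2 months against 335 at 4 months in females, a ratio of 40.6 (95% counting interval 20.4 to 94.9). It had 4 against 206 in males, a ratio of 36.9 (95% counting interval 14.2 to 137).

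Plaque-associated microglial genes rose in 24 of 30 cases in each sex between 2 and 4 months (26 in females and 27 in males adjusted over the list alone, medians 1.30 and 1.20, camera adjusted p with an estimated correlation 3.2e-12 and 1.5e-10). Homeostatic microglia had 15 of 16 genes risen in each sex, and complement 7 of 15 in females and 6 in males. Antigen presentation had 15 of 20 and 8, the interferon list 24 of 25 and 15, and reactive astrocytes 8 of 21 and 7. All of these lists passed in both sexes with either correlation. Other lists passed only with the preset correlation. In females neuronal (median −0.07), vascular (−0.09), meningeal (−0.26) and immediate early genes (−0.19) were lower by camera (adjusted p = 0.0319, 0.0201, 0.00549 and 8.2e-04). Astrocyte markers (0.06) and blood genes (0.41) were higher in females (camera adjusted p = 0.00549 and 0.0445). The neuronal list lost its call in 4 fits without 1 library, the blood list in 5, and the vascular and immediate early lists in 1 each. In males oligodendrocyte precursors were lower (median −0.13) and mitochondrially encoded genes higher (0.17, camera adjusted p = 6.2e-04 and 1.8e-05). Myelin genes fell further: Cldn11 went from 186 ± 12.9 to 145 ± 6.24 CPM in females (edgeR adjusted p = 8.0e-05) and from 202 ± 7.72 to 141 ± 11.9 CPM in males. The oligodendrocyte list lost 6 of 22 genes in females and 7 in males (13 and 14 adjusted over the list alone, camera adjusted p = 3.3e-06 and 4.0e-11, adjusted p = 0.250 and 0.0592 with an estimated correlation). The neurogenesis list lost 4 of 16 in each sex (8 and 7 adjusted over the list alone, medians −0.25 and −0.23, adjusted p = 0.0087 and 0.0305 with an estimated correlation by camera). In males cholesterol synthesis had 6 of 19 genes risen (15 adjusted over the list alone, median 0.27, camera adjusted p = 2.8e-11, adjusted p = 0.0902 with an estimated correlation). Fdft1, the squalene synthase, rose from 72.2 ± 3.08 to 92.3 ± 3.68 CPM. Choroid plexus markers moved with this step, with list medians of −0.49 in females and −1.27 in males (camera adjusted p = 0.0323 and 5.4e-11, adjusted p = 0.714 and 0.227 with an estimated correlation). In females that call was lost in 3 of 10 fits without 1 library (highest camera adjusted p = 0.417, without 4-month female 5).

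Between 1 and 2 months the myelin and immature neuron genes fell, in both sexes. Cldn11 fell in females from 368 ± 32.9 to 186 ± 12.9 CPM (mean ± SD, n = 5, edgeR adjusted p = 8.2e-15) and in males from 362 ± 29.5 to 202 ± 7.72 CPM (edgeR adjusted p = 7.8e-13). Il33, an alarmin cytokine made in mature oligodendrocytes and astrocytes, rose from 14.4 ± 1.86 to 41.3 ± 3.98 CPM in females and from 17.6 ± 3.58 to 42.2 ± 4.13 CPM in males (edgeR adjusted p = 6.5e-13 and 9.9e-12). The edgeR fit called 120 genes higher and 305 lower in females, and 524 higher and 586 lower in males. All 1-month males carried 1 prefix and all 2-month males another, so age and prefix cannot be told apart in the counts of males. The sexes shared 57 risen genes (3.80 by chance) and 186 fallen genes (10.8 by chance).

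The oligodendrocyte list lost 15 of 22 genes in females and 16 in males between 1 and 2 months (medians −0.68 and −0.69, camera adjusted p = 3.6e-60 and 3.3e-36, and 2.7e-05 and 7.4e-04 with an estimated correlation). Oligodendrocyte precursors lost 8 of 16 in each sex (12 and 11 adjusted over the list alone), and the neurogenesis list 5 in females and 8 in males (9 and 10 adjusted over the list alone), with both lists passing under either correlation. Of 5 blood genes 4 fell in each sex (medians −1.33 and −1.06, camera adjusted p = 0.00134 and 0.0147 with an estimated correlation). Hba-a1, an alpha-globin gene, fell from 113 ± 18.8 to 45.2 ± 4.70 CPM in females. How reads shared by the paired globin genes were counted is not given in the sources used here. In females 4 of 30 plaque-associated microglial genes rose (13 adjusted over the list alone, median 0.22, camera adjusted p = 7.1e-07, and 0.0373 with an estimated correlation). Ctsz, a lysosomal cathepsin, rose from 18.5 ± 1.12 to 24.2 ± 1.52 CPM. Cst7 had 3 counts in the 1-month and 66 in the 2-month females, a ratio of 17.4 (95% counting interval 5.70 to 86.6). In males 2 members of this list rose and 2 fell (camera adjusted p = 0.912). Cst7 was among the risen, with 6 counts in the 1-month and 18 in the 2-month males, a ratio of 4.54 (95% counting interval 1.72 to 13.96, edgeR adjusted p = 0.0380), and lost its call in 5 of 10 fits without 1 library. Complement (median 0.32) and antigen presentation (0.31) also rose in females (camera adjusted p = 0.0340 and 0.0488 with an estimated correlation). Only with the preset correlation did further lists pass. Choroid plexus markers had medians of 0.54 in females and 0.85 in males (camera adjusted p = 0.0150 and 0.00348), and immediate early genes 0.17 and 0.18 (camera adjusted p = 0.0387 and 0.0489). In females interferon genes (median 0.11) and mitochondrially encoded genes (0.13) passed as well (camera adjusted p = 0.0326 and 9.0e-06). Of these the choroid plexus list lost its call in 3 fits without 1 library in females and 1 in males, the immediate early list in 4 and 6, and the interferon list in 4. In males antigen presentation (median 0.15) and ependymal markers (0.54) were higher by camera (adjusted p = 0.0121 and 0.00253), the former not without 2-month male 3 (0.0553). Astrocyte (−0.07), meningeal (−0.37) and nuclear oxidative phosphorylation genes (−0.06) were lower in males (camera adjusted p = 0.0121, 1.7e-04 and 0.00579). The difference between the sexes in this step was not tested. Cholesterol synthesis lost 5 of 19 genes in females and 8 in males (10 and 13 adjusted over the list alone, medians −0.22 and −0.28, camera adjusted p = 4.3e-10 and 5.0e-13, adjusted p = 0.145 and 0.116 with an estimated correlation). Hmgcs1, which makes HMG-CoA for sterol synthesis, fell from 496 ± 69.1 to 336 ± 29.9 CPM in males.

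At 4 months, the age the series title names for the comparison of the sexes, females had higher levels of microglial, interferon-responsive and antigen presentation genes. Ctsz (ENSMUSG00000016256, chromosome 2, 174427493 to 174439039) stood at 60.3 ± 3.53 CPM in females and 41.9 ± 5.35 CPM in males (mean ± SD, n = 5, log2 ratio 0.53, SE 0.0733, edgeR adjusted p = 1.6e-05). Cst7 stood at 26.6 ± 2.74 against 16.8 ± 1.71 CPM (log2 ratio 0.67, SE 0.119, edgeR adjusted p = 0.00191). Oasl2 (ENSMUSG00000029561, chromosome 5, 114896936 to 114912234), an interferon-induced 2'-5'-oligoadenylate synthetase-like protein, stood at 14.1 against 8.11 CPM (log2 ratio 0.82, SE 0.138, edgeR adjusted p = 7.0e-04). The inducible heat shock genes Hspa1a and Hspa1b were lower in females, at 27.3 ± 3.81 against 52.8 ± 16.4 CPM and 25.7 ± 3.66 against 55.7 ± 18.8 CPM (edgeR adjusted p = 0.00316 and 7.0e-04). These neighbouring paralogs on chromosome 17 share most of their sequence, and how their shared reads were counted is not given in the sources used here.

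Of 30 plaque-associated microglial genes, 7 were higher in 4-month females and none lower, 22 when adjusted over the list alone (median 0.32, camera adjusted p = 5.4e-17, and 6.8e-04 with an estimated correlation). Besides Ctsz and Cst7 these included Trem2 at 39.3 ± 3.31 against 28.4 ± 4.28 CPM (edgeR adjusted p = 0.00343) and Cd68, a lysosomal membrane protein of phagocytes, at 20.6 ± 1.60 against 13.9 ± 2.64 CPM. Homeostatic microglia had 4 of 16 genes higher (9 adjusted over the list alone, median 0.26, camera adjusted p = 1.1e-08, and 0.0156 with an estimated correlation). The fractalkine receptor Cx3cr1 stood at 86.2 ± 6.60 against 72.1 ± 6.78 CPM (edgeR adjusted p = 0.0113, 0.0695 without female 2 and 0.0508 without male 3). Of 25 interferon-responsive genes 6 were higher (19 adjusted over the list alone, median 0.50, camera adjusted p = 6.2e-17, and 0.00176 with an estimated correlation). Stat1, a transcription factor of interferon signalling, had a log2 ratio of 0.48, and Ifit3 stood at 28.6 ± 7.41 against 18.6 ± 1.09 CPM. Antigen presentation had 5 of 20 genes higher (14 adjusted over the list alone, median 0.36, camera adjusted p = 2.9e-10, and 0.0125 with an estimated correlation). H2-D1, an MHC class I heavy chain, stood at 62.4 ± 10.6 against 45.2 ± 5.41 CPM. Complement had 4 of 15 genes higher (7 adjusted over the list alone, median 0.38, camera adjusted p = 2.2e-07, and 0.0156 with an estimated correlation), and C4b stood at 90.2 ± 5.94 against 62.4 ± 10.9 CPM. Gfap stood at 856 ± 49.3 against 695 ± 84.9 CPM (edgeR adjusted p = 0.00426). The reactive astrocyte list did not pass (camera adjusted p = 0.346), and its median of 0.11 and upward test differed in sign from its mean of −0.19. Lcn2 was lower in females at 0.167 ± 0.132 against 5.07 ± 7.79 CPM (edgeR adjusted p = 0.0406), but the call was lost in 7 of the 10 fits without 1 library. These were the fits without each female (edgeR adjusted p = 0.0725 to 0.104), without male 3 (0.0626) and without male 2 (0.183). The log2 ratio was −4.75, −3.15 without male 2 and between −4.50 and −5.27 without any other library. Over 18 alternatives the adjusted p ranged from 0.00176 to 0.225.

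Choroid plexus markers moved with these groups. All 20 were numerically higher in 4-month females with a median of 1.19 and none passing by edgeR (camera adjusted p = 1.6e-10, adjusted p = 0.342 with an estimated correlation). The mean log2 CPM of the list was 4.43 ± 1.02 in females and 2.39 ± 2.00 in males. Ependymal markers had a median of 0.33 (camera adjusted p = 0.0082, adjusted p = 0.461 with an estimated correlation) and neuronal markers a median of −0.05 (camera adjusted p = 0.0134, adjusted p = 0.342 with an estimated correlation). The ependymal list did not pass without male 5 (camera adjusted p = 0.0930) and the neuronal list without female 2 (camera adjusted p = 0.0514). The other lists did not pass by camera, with adjusted p of 0.799 for astrocytes, 0.895 for interneurons, 0.353 for oligodendrocytes, 0.118 for their precursors, 0.408 for vascular markers, 0.180 for meninges, and 0.518 for neighbouring brain regions. It was 0.192 for hippocampal subfields, 0.434 for immediate early genes, 0.597 for neurogenesis, 0.895 for cholesterol synthesis, 0.0763 for glucocorticoid-responsive genes, and 0.199 for amyloid processing. It was 0.781 and 0.346 for nuclear and mitochondrial oxidative phosphorylation genes, 0.0542 for blood and 0.340 for the transgene-related list. Of 8 X escape genes 5 were higher in females, such as the translation factor gene Eif2s3x at 189 ± 3.29 against 121 ± 5.55 CPM. All 4 Y-linked genes tested were higher in males.

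Of the 168 genes called at 4 months, 92 were higher and 76 lower in females, or 86 and 72 without the sex-linked lists. On FPKM 102 were higher and 12 lower, and with the choroid plexus covariate 64 and 66. Of the 3 animal-code prefixes of this age 2 occurred in both sexes. The mean log2 CPM of the plaque-associated list was higher in females by 0.37 within a prefix of 2 females and 3 males and by 0.40 within a prefix of 1 female and 2 males. The fit with the prefix as a block used only the 10 libraries of 4 months, so it differs from the fit of 30 libraries in more than the block. It called 160 genes, 87 of them shared with the 168. They held 10 of the plaque-associated list (7 in the fit of 30 libraries), 1 of homeostatic microglia (4), 2 of interferon (6), 1 of antigen presentation (5) and 0 of complement (4). The medians of these lists changed little, to 0.37, 0.27, 0.43, 0.37 and 0.44 from 0.32, 0.26, 0.50, 0.36 and 0.38. All 5 passed with the block (camera adjusted p = 2.3e-17, 4.5e-07, 4.8e-11, 8.4e-08 and 3.7e-06). C4b, H2-D1, Ifit3, Stat1, Gfap, Hspa1a and Hspa1b did not pass with that block. Within the 2 shared prefixes C4b stood at 83.0 and 94.4 CPM in females against 52.9 to 66.6 CPM in males, and at 93.1 against 56.5 and 79.5 CPM. Gfap stood at 789 and 828 against 585 to 735 CPM, and at 913 against 655 and 812 CPM. For these genes the lost calls do not by themselves show an effect of the prefix. Without a block the fit of the 10 libraries of 4 months alone called 34 genes. Leaving out 1 library changed the count of 168 to 70 without female 3, 80 without female 2, 98 without male 5 and 111 without male 3.

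At 2 months 12 genes differed between the sexes by edgeR, 8 higher and 4 lower in females. Outside the sex-linked lists these were Oasl2, Fastkd5, which processes mitochondrial RNA, and X-linked Gm2223. Oasl2 stood at 5.53 ± 0.779 CPM in females and 2.38 ± 0.792 CPM in males (mean ± SD, n = 5, log2 ratio 1.14, edgeR adjusted p = 8.6e-04), and Gm2223 at 22.2 ± 1.67 against 15.3 ± 1.52 CPM. Cst7 at 1.05 ± 0.314 against 0.368 ± 0.241 CPM did not pass (edgeR adjusted p = 0.265). Only the X escape and Y-linked lists passed with an estimated correlation. With the preset correlation the complement list passed too (mean log2 CPM 2.47 ± 0.0894 in females and 2.27 ± 0.261 in males). It lost its call without several single libraries, among them male 4 and male 1 (camera adjusted p = 0.183 and 0.180). The plaque-associated list had a median of 0.21 with 4 genes adjusted over the list alone (camera adjusted p = 1.3e-05, adjusted p = 0.115 with an estimated correlation). Immediate early genes had a median of 0.47 with 12 of 22 adjusted over the list alone (camera adjusted p = 7.3e-11, adjusted p = 0.183 with an estimated correlation) and cholesterol synthesis 0.18 with 6 of 19 (camera adjusted p = 2.3e-08, adjusted p = 0.248 with an estimated correlation). The blood list had a median of −0.81 (camera adjusted p = 8.9e-08, adjusted p = 0.0999 with an estimated correlation), the meningeal list 0.33 (camera adjusted p = 1.1e-04, adjusted p = 0.438 with an estimated correlation). All 2-month males carried the same prefix as a single female, whose plaque-associated score was 0.41 above theirs. With the prefix as a block, in a fit of the 2-month libraries alone, Oasl2, Gm2223 and Fastkd5 did not pass. The contrast of the sexes in that fit rests on this 1 female, whose Oasl2 stood at 5.13 CPM against 1.68 to 3.70 CPM in the males. Fastkd5 also missed the threshold without female 3 (edgeR adjusted p = 0.0543) or male 1 (edgeR adjusted p = 0.0592). Without male 5 the count was 31.

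At 1 month 79 genes differed between the sexes by edgeR, 61 higher and 18 lower in females, and the microglial lists did not pass. Immediate early genes, which neurons transcribe within minutes of activity, were higher in females as a list. Of the 22 genes 3 passed, Fosb, Egr2 and Fosl2, and 13 did so adjusted over the list alone (median 0.38, camera adjusted p = 3.1e-10, adjusted p = 0.313 with an estimated correlation). Fosb, a subunit of the AP-1 transcription factor, stood at 12.6 ± 2.87 against 5.86 ± 0.728 CPM (mean ± SD, n = 5, log2 ratio 1.05, edgeR adjusted p = 0.0188). Egr2, a zinc finger transcription factor, stood at 4.97 ± 2.71 against 1.32 ± 0.265 CPM (edgeR adjusted p = 0.0365). Dusp5, a phosphatase that inactivates ERK, stood at 21.3 ± 3.61 against 12.4 ± 1.47 CPM (edgeR adjusted p = 0.00944). Kcnj2, an inward rectifier potassium channel, was lower at 12.8 ± 1.00 against 23.5 ± 3.40 CPM, and so was the matrix protein gene Thbs4 (log2 ratio −0.75, SE 0.143). Glucocorticoid-responsive genes had 2 of 19 members higher (camera adjusted p = 0.0106, adjusted p = 0.623 with an estimated correlation). The list did not pass without female 5, male 1 or male 5 (camera adjusted p = 0.0639, 0.0881 and 0.0528). Beside them, blood genes had a median of −0.62 (camera adjusted p = 1.2e-04, adjusted p = 0.313 with an estimated correlation). Choroid plexus markers had a median of 0.74 (camera adjusted p = 0.00427, adjusted p = 0.679 with an estimated correlation, and 0.0691, 0.0676 and 0.0758 without female 2, male 1 and male 2). Ependymal markers had a median of 0.44 (camera adjusted p = 4.6e-04, adjusted p = 0.435 with an estimated correlation). Hippocampal subfield genes had a median of −0.10 (camera adjusted p = 0.0106, adjusted p = 0.435 with an estimated correlation). Cholesterol synthesis had a median of 0.09 (camera adjusted p = 0.00222, adjusted p = 0.623 with an estimated correlation), and each of these 2 lists lost its call without 1 of the libraries. Mitochondrially encoded genes had a median of −0.10 (camera adjusted p = 0.00323, adjusted p = 0.623 with an estimated correlation). At this age no prefix occurred in both sexes, so prefix and sex cannot be told apart. The count was 36 without female 2, 37 without male 3, 46 without female 5 and 51 without male 4. The 3 passing immediate early genes each lost their call without some of the libraries. Egr2 did so in 9 of the 10 fits (highest edgeR adjusted p = 0.148, without female 4), Fosb in 4 (0.0673, without male 4) and Fosl2 in 3 (0.0626, without female 2).

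**Figure D2:**
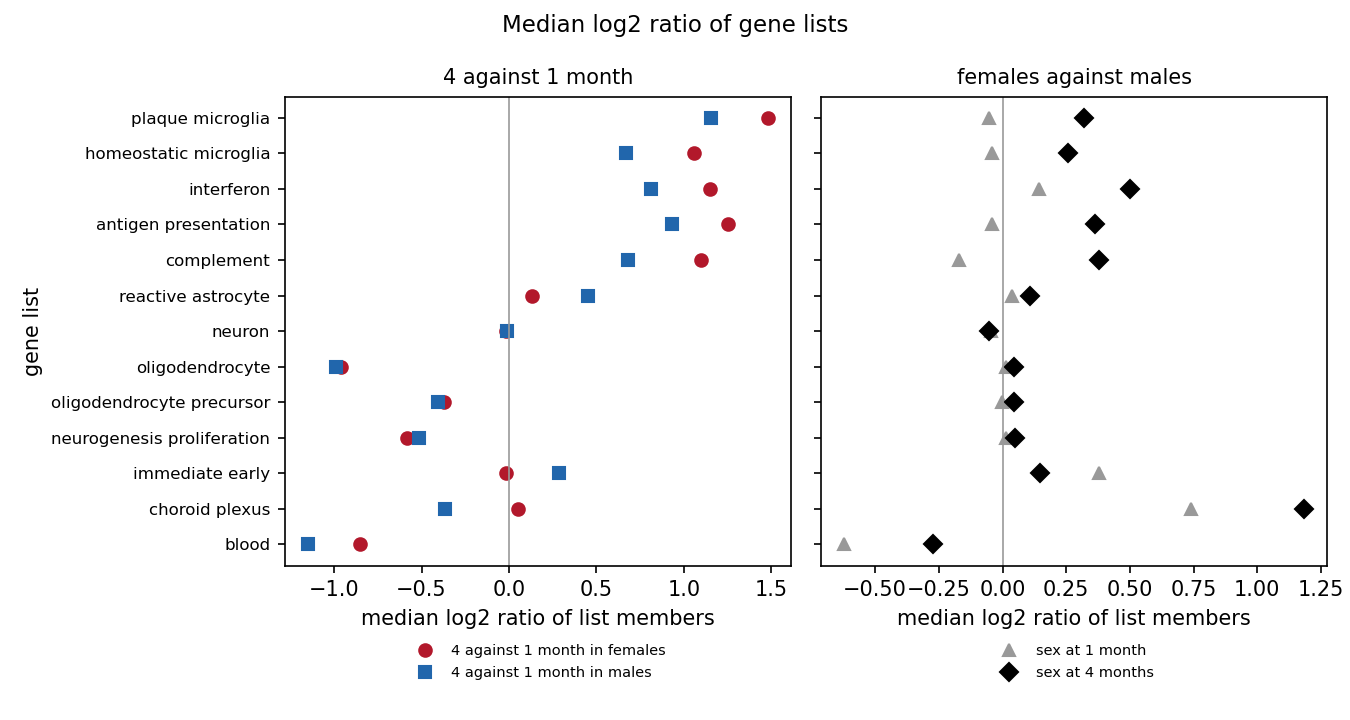
Median log2 ratio of the tested members of 13 gene lists, on a linear axis centred on 0. The left panel gives 4 against 1 month in females (circles) and males (squares), the right panel females against males at 1 month (grey triangles) and 4 months (black diamonds). The plaque-associated list lies at 1.48 and 1.16 in the left panel and at −0.05 and 0.32 in the right panel.

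The change between 1 and 4 months differed between the sexes, by the interaction term of the edgeR fit, for 191 genes. The difference was positive (female change minus male change) for 61 and negative for 130. On FPKM only 30 passed, 14 positive and 16 negative. Ctsz rose by 1.71 in females and 1.12 in males on the log2 scale (difference 0.59, edgeR adjusted p = 0.00568), and Gfap by 1.49 and 1.11 (edgeR adjusted p = 0.0173). Cst7, named here after its values were seen, did not pass (difference 1.12, edgeR adjusted p = 0.711). Nor did Trem2 (difference 0.52, edgeR adjusted p = 0.0866, but 0.0398 and 0.0468 without 1-month female 1 and male 2 and 0.0330 without 4-month male 4). Hspa1b had log2 changes of 0.11 in females and 1.65 in males (edgeR adjusted p = 0.00260). The plaque-associated list passed with 1 of 30 genes, 7 adjusted over the list alone (median 0.38, camera adjusted p = 2.5e-09, and 0.0276 with an estimated correlation). Homeostatic microglia passed with 2 of 16, 10 adjusted over the list alone (median 0.31, camera adjusted p = 1.4e-08, and 0.0287 with an estimated correlation). Complement passed with 1 of 15, 5 adjusted over the list alone (median 0.46, camera adjusted p = 8.8e-08, and 0.0276 with an estimated correlation). The interferon and antigen presentation lists had medians of 0.38 and 0.36 (camera adjusted p = 1.5e-05 and 7.4e-06, adjusted p = 0.131 and 0.112 with an estimated correlation). For the reactive astrocyte list the median of −0.06 and the mean of −0.18 differed in sign from the test. The count was 104 without male 3 and 107 without female 2 of the 1-month group. As no prefix occurred in both sexes at 1 month, prefix and sex cannot be told apart in that part of the term.

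**Figure D3:**
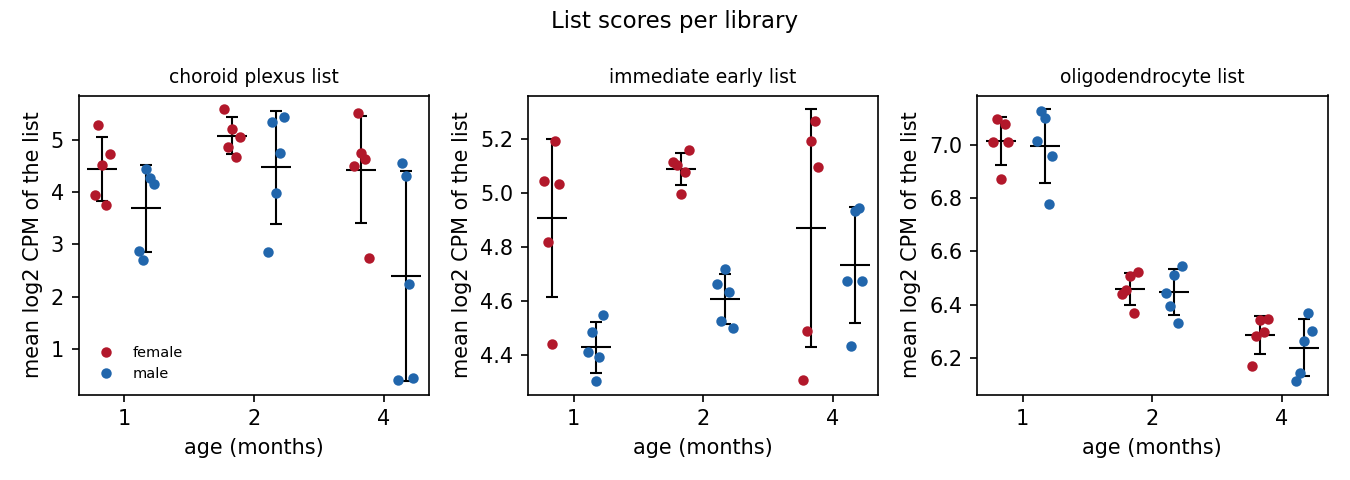
Mean log2 CPM of the choroid plexus, immediate early and oligodendrocyte lists in each of the 30 libraries by age in months and sex, on linear axes. Bars give the mean ± SD of 5 animals. The choroid plexus score has a SD of 2.00 in 4-month males and 0.353 in 2-month females. The oligodendrocyte score falls from 7.01 to 6.29 in females and from 6.99 to 6.24 in males between 1 and 4 months.

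The comparison with wild-type animals is available only from the authors' deposited tables. In the authors' deposited table for 4 months 894 genes were higher and 422 lower in 5XFAD at an adjusted p under 0.05. Log2 fold changes in the authors' deposited table were 5.05 for human APP, 4.86 for human PSEN1, 1.97 for Thy1, 3.99 for Cst7, 1.78 for Trem2, 1.47 for C4b and 1.27 for Gfap. The authors' deposited table for 2 months held 20 higher and 22 lower genes. The authors' deposited table for 1 month held 3, human PSEN1, human APP and Thy1. For the sexes apart at 4 months, the authors' deposited table gave 612 higher and 154 lower genes in females and 412 higher and 125 lower in males. Cldn11 had a log2 fold change of 0.02 (adjusted p = 0.898) in the authors' deposited table for 4 months. For females against males among 5XFAD animals of 4 months, the authors' deposited table held 133 genes higher and 94 lower in females. The authors' deposited table gave human APP at 0.25 (adjusted p = 0.00555) and human PSEN1 at 0.18 (adjusted p = 0.317) on the log2 scale. Of 16536 genes tested in both, 168 passed in the edgeR fit and 210 in the authors' deposited table, and all 143 shared genes went the same way. Of 2217 proteins with an adjusted p, the authors' deposited table held 2 past 0.05 at 4 months, Gfap with a log2 ratio of 0.64 and App (mouse entry) with a log2 ratio of 0.50. The authors' deposited protein tables held 0 at 1 month and 0 at 2 months, with 54 and 19 at an unadjusted p under 0.05.

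Quantitative PCR of human APP and human PSEN1 was deposited for 2 females and 2 males of 4 months. Relative to Eif4h, human APP stood at 6.68 ± 0.260 in females and 5.07 ± 0.380 in males (mean ± SD, n = 2, ratio 1.32), with a two-sided exact permutation p of 0.333, the smallest that the 6 splits allow (adjusted p = 0.667, exact permutation test). For this comparison the authors' deposited table gives a two-tailed p of 0.0385 and a one-tailed p of 0.0193. Human PSEN1 relative to Eif4h stood at 0.123 ± 0.0543 against 0.0979 ± 0.00221 (ratio 1.25, exact permutation p = 1), and without female 1 the ratio was 0.861. In the authors' deposited sheet of cycles 2 of the PSEN1 entries read PSEN2 and PSEN3 in 1 column, and they were taken as PSEN1 from the full label. Relative to Gapdh the ratios of females to males were 1.23 for APP and 1.18 for PSEN1. The deposited standard curves of the amplicons hold identical cycle values in 21 of 21 wells, so the efficiencies behind these ratios are uncertain.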

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

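Of the tests below, the choroid plexus and prefix tests of the first pattern, the prefix test of the second, and of the third the small RNA test and the choice of 1 library as its cause were chosen only after the result was seen. The fits without 1 library and the splits of samples were chosen before. The alternatives were too, except those on FPKM, those on libraries of low Ttr or low counts, and the list tests with blocks.

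Microglial and interferon genes were higher in females than males at 4 months, with a plaque-associated list median of 0.32 (camera adjusted p = 5.4e-17, with a range of 1.4e-18 to 6.8e-04 over 15 alternatives). A choroid plexus share that differed between the sexes (all 20 markers numerically higher in females, median 1.19) is argued against as the whole cause, since with the choroid plexus score as a covariate the list passed with a median of 0.27 (camera adjusted p = 1.4e-12). A difference between prefixes as the whole cause is argued against as well, since with the prefix as a block the list passed with a median of 0.37 (camera adjusted p = 2.3e-17) and females lay higher within both shared prefixes, by 0.37 and 0.40. Of 100 splits 2, with the real one included, reached the 168 genes. The highest other, 750 genes, parts the commonest prefix from the others and points to a structure of the samples. The animals are therefore not interchangeable, and the splits cannot settle whether chance made the count. In fits of the 4-month libraries alone 160 genes were called between the sexes with the prefix as a block and 34 without it. An effect of sex itself, or of human APP (higher in females by 0.25 in log2 in the authors' deposited table), was not tested and stays open, as does what the prefix stands for.

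Immediate early genes were higher in females at 1 month, with a list median of 0.38 (camera adjusted p = 3.1e-10). That 1 library alone made the pattern is argued against, as the list passed in 10 of 10 fits without 1 library (highest camera adjusted p = 1.2e-07, without female 4), although over all 14 alternatives the adjusted p ranged from 1.4e-16 to 0.313, the highest with an estimated correlation. Because 0 males of 1 month share a prefix with a female, prefix and sex cannot be told apart for these genes. A chance split of the animals is argued against for the count of 79 genes between the sexes at this age. Of 100 splits 1, the real one, reached it and the highest other called 3, but the splits do not tell sex from prefix. Sex, and the handling of the groups before tissue was taken, may each account for the pattern and were not tested.

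Rn7sk, Gm24447 and Gm26315, structural RNAs of 1 family, and Lcn2 stood far above the rest in replicate 2 of the 4-month males, at 181, 108, 102 and 18.6 CPM compared with 3.56 to 15.1, 2.11 to 8.80, 1.96 to 8.54 and 0.363 to 4.85 CPM in the other males. Without this library 0 of the 3 RNAs kept their call between 4 and 1 months (edgeR adjusted p = 0.570, 0.538 and 0.550), and their log2 fold changes were 0.52, 0.54 and 0.51 against 3.16, 3.17 and 3.13 with it, consistent with a cause within that library. Over 20 alternatives their adjusted p reached down to 7.1e-04, 6.1e-04 and 6.1e-04, while Lcn2 between the sexes lost its call without it (edgeR adjusted p = 0.183, with a range of 0.00176 to 0.225 over 18 alternatives) and its log2 ratio moved to −3.15 from −4.75, against −4.50 to −5.27 without 1 of the other libraries, but the ratio left is large, so whether that library is the whole cause cannot be decided. Whether a wider gain of small RNAs could be the cause cannot be told apart, since 50 of 54 such genes overlap another gene, among them Rn7s6 at 30.5 CPM in this library against a mean of 3.98 CPM and Gm22009 at 17.7 against 7.90 CPM, and the 4 that stand apart had a median log2 difference of −0.13. No biological explanation was tested.

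The interaction of sex and age passed for further genes and lists, each a difference between the changes of females and males from 1 to 4 months. The gene differences with edgeR adjusted p under 0.05 were 2.09 for Psmb9, 1.43 for Icam1, 1.21 for Adgre1, 1.04 for Fcgr2b, 0.93 for Kcnj2 and 0.93 for Thbs4. They were 0.70 for P2ry13, 0.59 for Ctsz, 0.37 for Cx3cr1, 0.72 for C4b, 0.61 for Stat1 and 0.37 for Gfap. On the other side they were −1.54 for Hspa1b, −1.39 for Hspa1a, −0.98 for Slc5a3, −1.31 for Tnfrsf25, −0.75 for Homer1, −1.20 for Fosb, −0.40 for Errfi1, −0.84 for Cys1, −0.80 for Banp and −0.52 for Fastkd5. Without 1 library C4b lost its call in 3 of 20 fits (highest edgeR adjusted p = 0.0619, without 1-month female 2), Fcgr2b in 4 (0.0898, without 1-month female 2), Errfi1 in 3 (0.0720, without 1-month female 5) and Fosb in 12 (0.0800, without 1-month male 4). List medians of the difference were 0.38 for plaque-associated microglia, 0.31 for homeostatic microglia, 0.46 for complement, 0.36 for antigen presentation and 0.38 for interferon. They were 0.46 for choroid plexus, −0.35 for immediate early genes, −0.0861 for cholesterol synthesis and −0.40 for glucocorticoid response. Of these the last 4 did not pass with an estimated correlation (camera adjusted p = 0.897, 0.508, 0.897 and 0.374), nor did antigen presentation and interferon (0.112 and 0.131). Without 1 library the choroid plexus list lost its call in 3 of 20 fits and cholesterol synthesis in 6. Of the genes above, Icam1, Adgre1, Kcnj2, Thbs4, P2ry13, Slc5a3, Fosb and Errfi1 were also called between the sexes at 1 month, where no prefix occurs in both sexes, so prefix and sex cannot be told apart in the 1-month part of this term. At 1 month Adgre1 lost its call in 9 of 10 fits without 1 library, Icam1 in 7, P2ry13 in 6, Fosb in 4 and Errfi1 in 1. The interaction count of 191 was reached by 1 of 100 splits, the real one, with 2 as the highest other. These splits exchanged the sexes within each age. They address the absence of any sex difference and not the absence of an interaction alone.

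Single libraries lay apart from the other 4 of their group in 20 values. In all, 339 groups of gene values gave 16 such libraries, 168 groups of list scores gave 3 and 6 groups of total counts gave 1, and chance gives about 1 in 20 groups. Replicate 1 of the 4-month males had 7.92 M counts against 13.5 M to 14.6 M in the others, and Eif2s3x at 112 CPM (123 to 126). Among 4-month males Osmr stood at 18.6 CPM in replicate 2 (9.79 to 10.9), the neuron score at 8.75 in replicate 2 (8.79 to 8.80) and Fcrls at 36.5 CPM in replicate 3 (24.9 to 27.2). Among 4-month females C1qc stood at 85.4 CPM in replicate 3 (71.5 to 74.2), Irf7 at 3.85 CPM in replicate 1 (4.99 to 5.26), Slco1a4 at 41.4 CPM in replicate 1 (46.2 to 47.0) and Thy1 at 2633 CPM in replicate 5 (2240 to 2277). Among 2-month males the interferon score stood at 1.52 in replicate 1 (1.37 to 1.41) and the neurogenesis score at 3.41 in replicate 3 (3.26 to 3.29). Among 1-month females Ggta1 stood at 6.36 CPM in replicate 3 (4.22 to 4.72), Mal at 577 CPM in replicate 3 (660 to 693) and Trem2 at 10.7 CPM in replicate 1 (6.50 to 7.55). Among 1-month males Fosb stood at 4.58 CPM in replicate 4 (5.98 to 6.32) and Rab7b at 7.55 CPM in replicate 2 (3.88 to 4.70).

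For the remaining counts, chance cannot be excluded for the size of the count of 12 genes between the sexes at 2 months, which 5 of 100 splits reached. It does not put in doubt the 9 of them in the sex-linked lists, such as Xist at 921 ± 68.4 against 1.46 ± 0.555 CPM. The highest other split, of 4 females with 1 male against the rest, called 55. With the prefix as a block the contrast of the sexes rests on the 1 female that shares a prefix with the males. A chance split of the animals is argued against for 4 against 1 month in females (2276 genes, highest other 466) and males (3331, highest other 419), where the real split alone, 1 of 100, reached its count. The same holds for 4 against 2 months in females (613, highest other 388) and males (703, highest other 153), and 2 against 1 month in females (425, highest other 72) and males (1110, highest other 101). These splits do not tell age from prefix, as no prefix occurred at more than 1 age.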

How the results depend on the processing

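The FPKM fits, the fits without libraries under 100 CPM of Ttr or under 7 M counts, the list tests with blocks and the equal qPCR efficiency were tests chosen only after seeing the data. Of 286 named gene results 256 were called in the main fit, and none of these changed direction in any setting. None of the others was called in the opposite direction, and their directions were not compared where no call was made. All 286 kept their side of the threshold with DESeq2 size factors. Most of these results were named for a large change or a low p, so their stability does not stand for all called genes. Of the 256 called, 6 lost their call without a filter, 4 with the replicate block, 12 with the choroid plexus covariate and 14 with voom. Among called results that a setting covered, 30 of 252 lost their call with their own libraries alone and 38 of 254 with FPKM. With the prefix block, which also used those libraries alone, 22 of 44 did. Of 3100 fits without 1 library, those of results not called included, 182 lost a call. Of 119 list calls 62 lost theirs with an estimated correlation, and 76 of 1280 list fits without 1 library did so. List calls were also lost in 10 of 111 cases with the choroid plexus covariate, 8 of 93 without libraries under 7 M counts, 7 of 47 without those under 100 CPM of Ttr (2 of them reversed) and 3 of 19 with the prefix block (1 reversed). Counts of called genes were within 1.5 times the main count except as follows, and the causes were not tested. With a comparison's own libraries alone 34 genes differed between the sexes at 4 months, 20 at 2 months and 277 at 1 month, and 407 changed from 2 to 4 months in males. Without libraries under 100 CPM of Ttr 85 genes differed between the sexes at 4 months, 66 of them among the 168 of the main fit. Similar counts can also hide a turnover of genes. Of the 168, 78 were called again with the choroid plexus covariate and 72 on FPKM. DESeq2 called 23 at 2 months, 136 at 1 month and 287 in the interaction. Voom called 266 at 1 month and 679 from 1 to 2 months in females. FPKM gave 42 at 1 month, 244 and 647 from 1 to 2 months in females and males, and 30 in the interaction. FPKM moved the split of directions for sex at 4 months, the interaction and 4 against 1 month in males (above). The median of all genes moved too, to 0.041, 0.034 and −0.027 in log2. From 2 to 4 months the split was 395 and 38 in females (490 and 123 from counts, median −0.0030). In males it was 305 and 260 (486 and 217, median −0.034). With an estimated correlation the passing lists numbered 2 for sex at 2 months, 2 at 1 month, and 9 and 9 for 4 against 1 month in females and males. They numbered 7 and 7 for 4 against 2, 7 and 4 for 2 against 1 and 3 in the interaction. The direction reversed for the meningeal list between the sexes at 2 months with the prefix block (camera adjusted p = 0.862). It reversed for the choroid plexus list without libraries under 100 CPM of Ttr from 1 to 4 months in males (camera adjusted p = 0.952) and in the interaction (camera adjusted p = 0.862). Requiring a fold of 1.5 in the authors' deposited tables left 1 protein at 4 months, 9 genes between the sexes, 3 at 2 months, 173 and 92 in 4-month females and males and 180 at 4 months.

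Leaving out 1 library at a time, called genes ranged from 70 (without female 3) to 217 for sex at 4 months, 12 to 31 (without male 5) at 2 months, 36 (without female 2) to 99 at 1 month, 104 (without 1-month male 3) to 223 in the interaction. They ranged from 1865 to 2277 and 2803 to 3249 from 1 to 4 months in females and males, 475 to 619 and 526 to 761 from 2 to 4 months, and 288 to 391 and 740 to 1081 from 1 to 2 months. Sex at 4 months also fell to 80 without female 2, 98 without male 5 and 111 without male 3. Sex at 1 month fell to 37 without male 3, 46 without female 5 and 51 without male 4, and the interaction to 107 without 1-month female 2. Passing lists ranged from 10 to 13, 8 to 14 and 7 to 12 for sex at 4, 2 and 1 months. They ranged from 13 to 18 and 13 to 16 from 1 to 4 months, 13 to 16 and 12 to 16 from 2 to 4 months, 10 to 14 and 10 to 13 from 1 to 2 months, and 7 to 11 in the interaction. The qPCR ratios ranged from 1.25 to 1.39 and 1.14 to 1.32 for APP over Eif4h and Gapdh, and from 0.861 to 1.65 and 0.916 to 1.44 for PSEN1.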

Other observations

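The tests of the 4-month prefixes and of the plaque-associated list against the authors' table were chosen only after the values were seen, and the oligodendrocyte and Thy1 tests before.

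In the authors' deposited table for 4 months, sterol synthesis stood out beside the glial lists, with 12 of 20 cholesterol synthesis genes higher in 5XFAD (median log2 fold change 0.18). The authors' deposited tables for the sexes apart held 9 of them in females and 7 in males. Of 22 immediate early genes 6 were lower (median −0.17) in the authors' deposited table for 4 months, 4 in females and 0 in males. Their medians in the authors' deposited tables for the sexes apart were close, at −0.16 in females and −0.15 in males, and a difference was not tested. In the same authors' deposited table the interferon list had 26 of 26 members higher, plaque-associated microglia 23 of 30 and homeostatic microglia 15 of 16. Higher members in the authors' deposited table numbered 12 of 20 for antigen presentation, 9 of 15 for complement and 8 of 23 for reactive astrocytes. The authors' deposited table for 2 months held Apoe, the lipid carrier of astrocytes, at −0.22, the neuropeptide gene Npy at −0.27 and the sterol carrier gene Stard4 at 0.30 on the log2 scale.

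Within the 4-month animals, gene groups also differed between the commonest animal-code prefix (2 females and 3 males) and the other prefixes (3 females and 2 males). With sex in the fit, 821 genes differed by edgeR, 411 higher and 410 lower in the other prefixes, and 7 of them were among the 168 that differed between the sexes. The activity-regulated Egr1 stood at 180 CPM in the other prefixes and 116 CPM in the commonest (means, n = 5, log2 ratio 0.70, edgeR adjusted p = 0.0217). Mvd, an enzyme of the mevalonate pathway, stood at 14.7 ± 2.18 against 9.93 ± 2.13 CPM (edgeR adjusted p = 4.3e-04). The mitochondrial complex I gene mt-Nd2 stood at 4290 ± 238 against 5395 ± 132 CPM (edgeR adjusted p = 0.00104). By list, 4 of 22 immediate early genes were higher (median 0.34, camera adjusted p = 2.9e-10, adjusted p = 0.312 with an estimated correlation). Of 13 mitochondrially encoded genes 7 were lower (median −0.17, camera adjusted p = 6.6e-10, adjusted p = 0.312 with an estimated correlation), and 3 of 19 cholesterol synthesis genes higher (median 0.17, camera adjusted p = 1.2e-08, adjusted p = 0.312 with an estimated correlation). Oligodendrocyte genes had a median of 0.15 with 2 of 22 higher (camera adjusted p = 7.5e-05, adjusted p = 0.543 with an estimated correlation), and hippocampal subfield genes 0.09 with 4 of 18 higher (camera adjusted p = 8.9e-04, adjusted p = 0.312 with an estimated correlation). Ependymal markers had a median of −0.42 with 1 of 13 lower (camera adjusted p = 1.9e-04, adjusted p = 0.405 with an estimated correlation). Choroid plexus markers had a median of −1.33 beside them (camera adjusted p = 5.9e-08, adjusted p = 0.655 with an estimated correlation). The plaque-associated and interferon lists did not pass (camera adjusted p = 0.805 and 0.165).

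A hypothesis was that the fall of oligodendrocyte genes with age comes from the transgenes. Of the 16 fallen members in each sex, 0% had a change of at least 0.5 times the age change in the authors' deposited tables for 4 months. The medians in the authors' deposited tables were −0.02 in females and 0.04 in males against −1.05 and −1.13 between 1 and 4 months. That argues against the transgenes as the cause of the fall, and ordinary maturation stays open as untested. Of the risen plaque-associated members, 63.3% had such a change in the authors' deposited tables (16 of 25 in females and 15 of 24 in males). The medians were 1.19 and 0.94 there against 1.92 and 1.42 between 1 and 4 months, which goes with the transgenes as a cause of part of that rise. Ratios in the authors' deposited tables can be smaller than edgeR ratios of the same contrast. Between the sexes at 4 months the medians were 0.24 against 0.32 for this list and 0.28 against 0.50 for interferon. The share of 63.3% may therefore be too low, and the size of that part is not settled.

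Whether animals with more Thy1, whose promoter drives the transgenes, have a higher plaque-associated score could not be decided. Within the sexes, as deviations from the means of the groups over the 10 animals of 4 months, Pearson's r of log2 Thy1 CPM and the score was −0.36 (permutation p = 0.342, adjusted p = 0.684 over 2 relations) and Spearman's rho −0.15 (permutation p = 0.694), and r was −0.17 without the 2 animals farthest from the median of Thy1. Over the 30 animals of all groups, again as deviations, r was 0.06 (permutation p = 0.783) and rho 0.11 (permutation p = 0.592). Each sex alone would rest on 5 animals and was not computed.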
